A study of Ciona robusta with 12 samples.

How the data were processed

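Whole embryos of Ciona robusta, a tunicate, were profiled by RNA sequencing in 12 libraries. Per the labels, embryos received U0126 or its carrier DMSO, diluted 1:1000, at the 32-cell stage and were collected at the 64-cell or the 112-cell stage. This gives 4 groups of 3 replicates. The labels give the dose of U0126 as 4 mM, and it is repeated here as labelled; it is high for this inhibitor, and whether the unit is right could not be checked. Per the labels' protocols, each library came from the RNA of 300 embryos and was made with a stranded mRNA kit. The series' design text calls the replicates biological. The labels name no clutch, collection day or sequencing batch.

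Per the file headers, the authors deposited a table for each stage with 15284 gene models named by KH2012 identifiers. It holds read counts per gene normalized to library size, a signal that is never negative, and regularized log2 values that the authors made from the same counts. Per the submitters' processing notes, TopHat2 2.9.8b and DESeq 1.8.1 were used. The read counter, its strand setting, any filter and the genome build are not given in the sources used here. Values of overlapping genes, antisense genes and near-identical gene copies are therefore uncertain, since their reads can be split or shared in counting.

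Within each library, 100% of the deposited normalized counts were whole multiples of the library's smallest value, within a tolerance of 0.01, so whole reads were recovered by division. Median-of-ratios factors recomputed from these reads within each table differed from the deposited scaling by at most 4.85e-10 of its value. The recovered totals ran from 10623872 reads in DMSO replicate 3 at 112 cells to 15956670 reads in DMSO replicate 1 at 112 cells, and 13115 to 13857 genes had at least 1 read. A count of 0 in a library allows up to 3 reads, which is a normalized count of 2.42 to 3.29 depending on the library. This limit covers counting error only, because reads amplified without molecular identifiers are not independent molecules.

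The tests fixed before the data were examined assumed raw counts and named edgeR with TMM normalization. Each comparison was instead tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trend of the variance on the mean. This was chosen because the deposited values are normalized counts. The recovered reads also allowed the edgeR test, which was run as an alternative. Genes entered a fit with a normalized count of at least 10 in at least 3 of its libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the changes of low genes. The U0126 effect at a stage was fitted on the 6 libraries of that stage. The stage difference in DMSO embryos and the difference of the U0126 effect between stages used all 12 libraries, with a coefficient per group, after the recovered reads had been rescaled together by median-of-ratios factors. The tables were normalized separately by the authors, so levels set side by side across stages are on this joint scale. Stage coincides with the table, and possibly with a collection or sequencing batch. The overlap of the U0126 effects was tested with Fisher's exact test, two-sided, per direction, over genes tested at both stages. The 2 stages have no library in common.

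The replicate numbers of the labels run across all 4 groups, and libraries with the same number deviated together. Pearson's r of the deviations from the group means, across genes, was 0.451 to 0.833 for the 6 same-number pairs within a stage and 0.380 to 0.790 for the 12 same-number pairs across stages. It was -0.527 to -0.034 for pairs with different numbers. Each of the 12 libraries correlated best with a library of its own number. The numbers were therefore taken to pair the samples, from the data, as the labels do not say what a number shares. A fit with the replicate number as a block stands beside a result where it changed a call or moved a count by more than 1.5 times. In the blocked fit at 64 cells, which has 2 residual degrees of freedom, limma treated the spread as common to all genes of a given level, so its p-values are very small and rest on that assumption. No pair of replicates was a duplicate: the chi-square of their reads per gene was 18.8 to 128, where sampling noise alone gives about 1.

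The fitting steps were tested on simulated data in which 200 genes changed by known folds. The simulated libraries carried a replicate-number effect that was the same in all groups, as the block assumes. A gain with the block was thus built in, and its size cannot be carried over to the real libraries. For the U0126 effect at 64 cells (10704 genes) the test recovered 48% of 2-fold and 78% of 4-fold changes, and 93% and 98% with the block. At 112 cells (11183 genes) it recovered 4% of 2-fold and 64% of 4-fold changes without a false call, and 40% and 94% with the block, where 20 of 154 calls were false. For the stage difference (11498 genes) these shares were 20% and 72%, and 53% and 96% with the block. For the difference of effects between stages (11499 genes) they were 7% and 54%, and 31% and 77% with the block.

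Alternatives were the block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma-voom, other normalizations, filters and pseudocounts, the regularized log2 values, a joint fit of all libraries, and leaving out each library in turn. The 14 gene lists and 20 core genes that had been fixed by name before the data were examined were not used. The files do not pair KH identifiers with gene names, and 0 of the identifiers occurred in the RefSeq gene table used as reference, so no gene is named here. Genes are given by identifier, at most 2 per direction and comparison. They are those with the largest log2 fold change among called genes with a mean of at least 5 CPM in the higher group and with all libraries of a group beyond all of the other group (no such condition for the difference of effects). Where the block alone called genes in a direction, the condition was a change of the same sign in all 3 pairs.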

Results

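RNA sequencing measured transcript levels in whole embryos of the tunicate Ciona robusta. U0126 inhibits the kinase MEK and so blocks activation of ERK, the pathway through which FGF signals induce notochord and neural fates in the early ascidian embryo. Embryos exposed to U0126 or to the carrier DMSO from the 32-cell stage were collected at the 64-cell stage, soon after exposure, or at the 112-cell stage, with 3 replicates in each of the 4 groups. The libraries held 10623872 to 15956670 reads over genes. The first principal component carried 36.4% of the variance and separated the stages. The second, with 23.4%, set replicate 2 of every group apart from replicates 1 and 3. DMSO replicate 3 at 112 cells lay at 69.7 on the first component, beyond the other 112-cell libraries at 23.0 to 45.1.

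**Figure D1:**
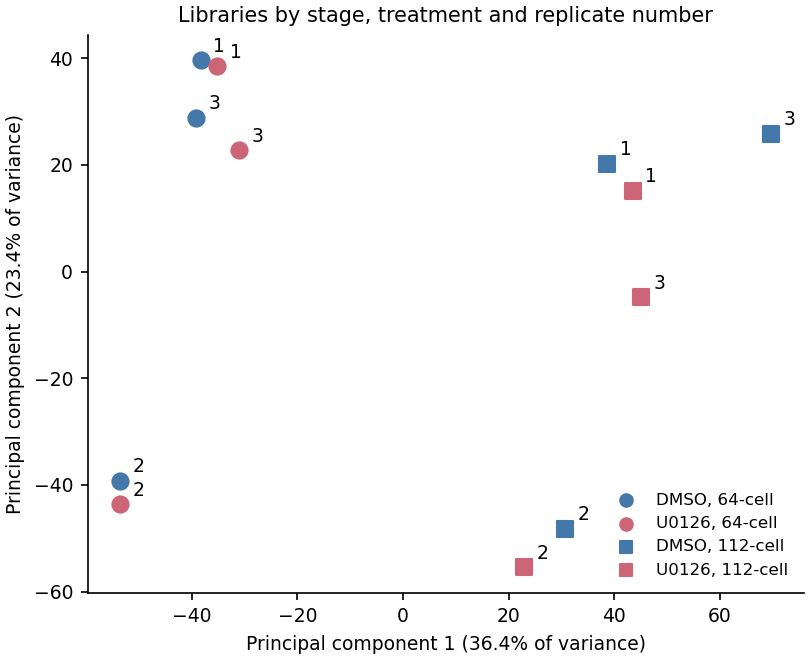
First against second principal component of log2(normalized count + 1) over 11650 genes, each point a library, coloured by treatment, shaped by stage and numbered by replicate. The axes carry 36.4% and 23.4% of the variance, and DMSO replicate 3 at 112 cells sits at 69.7 on the first.

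The first comparison asked which transcripts responded by the 64-cell stage. A pair of transcripts fell with U0126. KH.L128.12 fell from 209 ± 101 normalized counts in DMSO embryos to 5.97 ± 1.09 in treated embryos (SD, n = 3 each), a log2 fold change of -4.77 (SE 0.46, limma adjusted p = 0.0424). KH.S544.3 fell from 329 ± 21.4 to 56.9 ± 3.49 normalized counts, a log2 fold change of -2.51 (SE 0.18, limma adjusted p = 0.00758). Both were still low at 112 cells, where KH.L128.12 was at 371 ± 29.1 in DMSO and 9.11 ± 4.45 in U0126 embryos and KH.S544.3 at 731 ± 187 and 36.2 ± 5.75. These were the 2 genes called among 10792 tested by limma, and 96 genes had an unadjusted p under 0.05. No gene was called higher, while DESeq2 called 4 higher among its 18 and edgeR 0 among its 1.

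The replicate block changed this count to 146 genes, 75 higher and 71 lower, and edgeR with the same block called 132, of which 128 were shared. Most of these changes were small: the median log2 fold change was 0.74 for the higher and -0.82 for the lower genes, and 26 higher and 24 lower genes reached 2-fold. Some falls were larger: 6 lower and 2 higher genes reached 4-fold, and 4 lower and 0 higher genes reached 8-fold. Among the higher genes with a mean of at least 5 CPM and a rise in all 3 pairs, KH.L50.6 and KH.C9.872 rose the most under the block. KH.L50.6 was at 39.4 ± 16.3 normalized counts in DMSO and 189 ± 43.7 in U0126 embryos (log2 fold change 2.31), with a limma adjusted p of 1.04e-46 with the block and 0.504 without it, and 1.04e-46 to 1.00 over the alternatives. KH.C9.872 was at 36.5 ± 16.5 and 131 ± 48.2 (log2 fold change 1.84), with a limma adjusted p of 7.27e-24 with the block and 1.00 without it, and 7.27e-24 to 1.00 over the alternatives. At 112 cells, in separate libraries, 66 of the 71 lower genes also had a negative estimate (93.0%, against 50.5% of all genes) with a median of -1.15, and 65 of the 74 higher genes tested there a positive one (87.8%, against 49.5%) with a median of 0.83.

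Counts at 64 cells were sensitive to the libraries used. The unblocked count was 0 without DMSO replicate 2 or 3 or U0126 replicate 1 or 2, and 1 without U0126 replicate 3. KH.L128.12 did not pass the filter in the fits without a DMSO library, so its call was not tested there. The blocked count was 5 in the joint fit of all 12 libraries, which also changes the scaling, the genes tested and the block, and 112, 159 or 72 without replicate 1, 2 or 3 of both groups. KH.L128.12 kept its call under 7 of the 16 alternatives that tested it, and KH.S544.3 under 18 of 22. Under edgeR with TMM, the test fixed beforehand, KH.L128.12 missed the threshold (edgeR adjusted p = 0.0513).

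At the 112-cell stage, reached after a longer exposure, 83 of 11315 genes were called, 60 lower and 23 higher with U0126. The falls were the larger changes, with a median log2 fold change of -3.60 against 1.40 for the rises. At least 8-fold changes were seen in 40 of the 60 lower and 1 of the 23 higher genes. KH.C10.338 fell from 531 ± 143 normalized counts in DMSO embryos to 3.06 ± 2.64 in U0126 embryos (SD, n = 3 each; log2 fold change -7.19, SE 0.51, limma adjusted p = 0.00234). Its U0126 libraries held 6, 1 and 2 reads, near the floor. The size of its fold change thus depends on the pseudocount, with -7.45 at 0.5 and -5.60 at 8. KH.S1404.1 fell from 1011 ± 195 to 8.32 ± 4.92 (log2 fold change -6.87, SE 0.39, limma adjusted p = 0.00107). KH.C7.193 rose from 23.5 ± 6.24 to 119 ± 14.5 (log2 fold change 2.31, SE 0.30, limma adjusted p = 0.0262). KH.C9.131 rose from 263 ± 52.5 to 1222 ± 251 (log2 fold change 2.21, SE 0.23, limma adjusted p = 0.0108). At 64 cells KH.C10.338 was at 35.1 ± 16.05 in DMSO and 2.50 ± 2.54 in U0126 embryos, and KH.S1404.1 at 108 ± 47.1 and 8.32 ± 7.76.

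**Figure D2:**
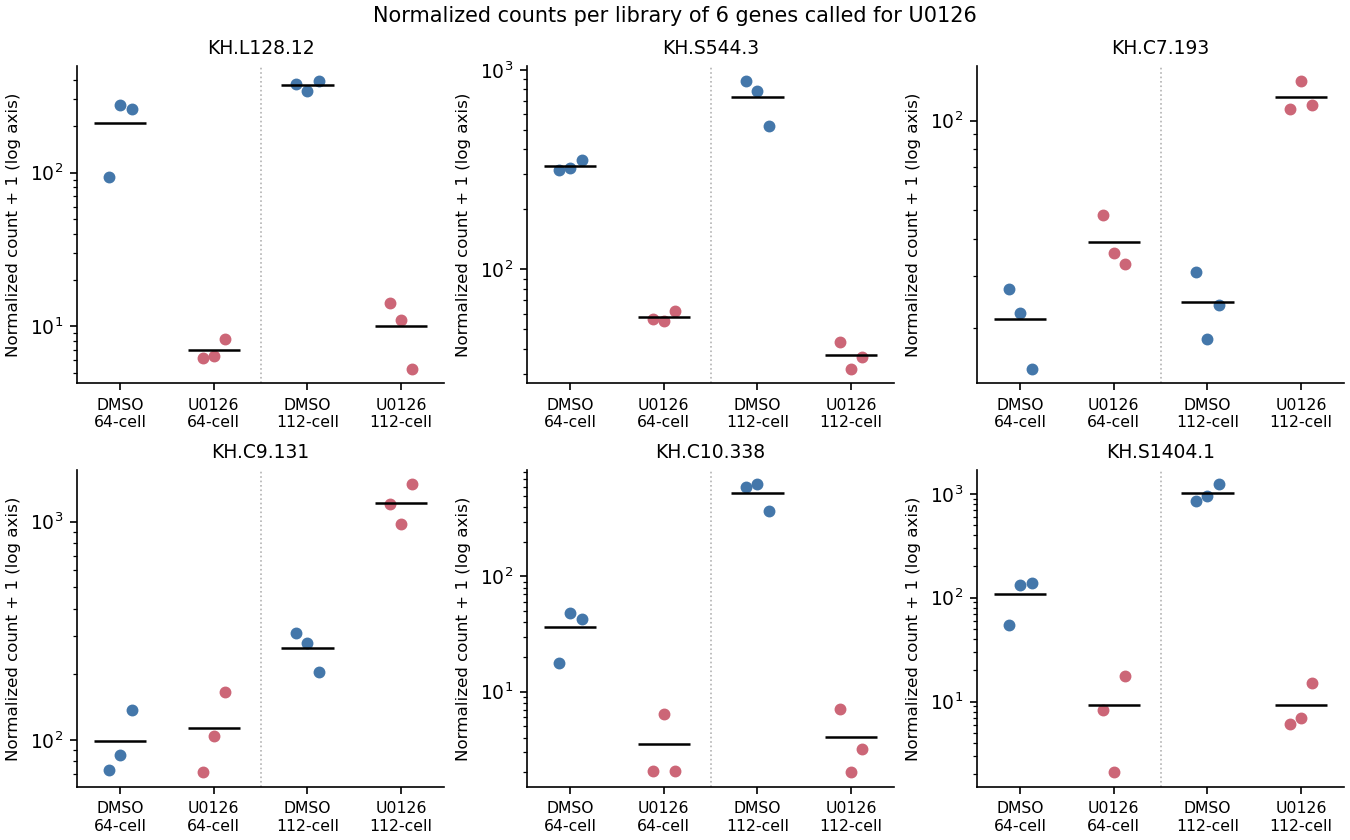
Normalized counts + 1 (log axis) of 6 genes called for U0126, each point a library and each line a group mean of 3, with DMSO in blue and U0126 in red. KH.C10.338 averages 531 normalized counts in DMSO and 3.06 in U0126 embryos at 112 cells, and KH.C9.131 averages 263 and 1222. The stages were normalized separately, as the dotted line marks.

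With the replicate block, 49 genes were called at 112 cells, 45 lower and 4 higher, 43 of them shared with the unblocked calls. Both named falls were kept. Both named rises were not: the limma adjusted p became 0.0702 for KH.C7.193 (1.77e-08 to 0.162 over its alternatives) and 0.0575 for KH.C9.131 (1.42e-14 to 0.0739). DMSO replicate 3 had 210 genes at least 4-fold under all 11 other libraries. Without that library 119 genes were called, 62 lower and 57 higher. Of the 60 lower genes 38 kept their call, as did all 23 higher genes. Some lost calls may come from the filter. With a DMSO library left out, a gene under 10 in all U0126 libraries cannot reach the 3 libraries it asks for. On the joint scale 26 of the 60 lower genes averaged under 10 in U0126 embryos at 112 cells. KH.C10.338 was not tested in the fits without a DMSO library. The count was 16 without DMSO replicate 1, 18 without DMSO replicate 2, and 30, 34 or 25 without U0126 replicate 1, 2 or 3. In these 5 fits 1, 0, 0, 3 and 0 genes were called higher, so the 23 rises were mostly lost when any library other than DMSO replicate 3 was left out. The blocked count was 83 (27 higher, 56 lower) without replicate 1 of both groups. It was 194 (120 higher, 74 lower) without replicate 2 and 1201 (795 higher, 406 lower) without replicate 3. Higher genes thus outnumbered lower ones in the last 2 of these fits. Each had 1 residual degree of freedom, and genes under 10 in both remaining libraries of a treatment could not enter. KH.C10.338 was in none of these fits and KH.S1404.1 not in the last, so they cannot settle which direction predominates.

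The genes called at 112 cells were then followed through all 4 groups on the joint scale. The 60 lower genes had a median level of 35.2 in DMSO embryos at 64 cells and 353 at 112 cells, while in U0126 embryos it was 13.8 and 14.7. Between the stages, 52 of the 60 rose in DMSO embryos, whereas 6 rose and 4 fell in U0126 embryos. The median log2 change between the stages was 3.0 in DMSO and 0.14 in U0126 embryos, or 0.07 with the 3 genes that had no read in a whole group set at their bound. At 64 cells 35 of the 39 lower genes tested had a negative U0126 estimate, with a median of -0.77. The 23 higher genes had medians of 69.6 and 331 in DMSO embryos and 132 and 1161 in U0126 embryos, and 17 rose between the stages in DMSO and 22 in U0126 embryos.

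**Figure D3:**
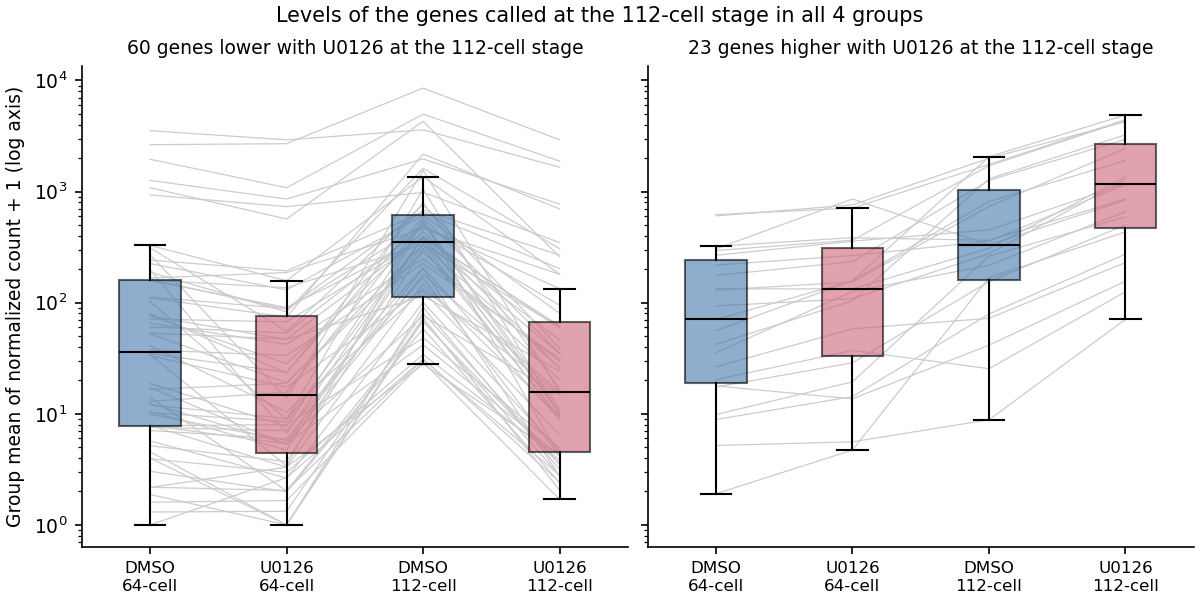
Group mean of normalized count + 1 on the joint scale (log axis) for the 60 genes lower and the 23 genes higher with U0126 at 112 cells, each grey line a gene, with boxes for the median and quartiles and whiskers to the furthest gene within 1.5 times the box length. The lower genes have medians of 35.2 and 353 in DMSO embryos and 13.8 and 14.7 in U0126 embryos at the early and late stage.

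DMSO libraries at 112 cells enter both the U0126 effect and the DMSO stage change, so chance alone links these. All 60 lower genes had a positive stage change, and in 50 simulations without any effect of stage or treatment 83.6% of the 60 lowest genes did (75% to 91.7%). The covariance of the estimates across genes was -0.161, against -0.036 in the simulations (correlations -0.33 and -0.50). Lists drawn independently would share 3.30 genes where 52 were shared, and 1.27 where the 17 higher genes were. With 3 DMSO libraries, the controls could not be divided into parts of at least 2. Part of the excess of the 52 lower genes may therefore come from the shared libraries. Their link was negative in the simulations (correlation -0.50), so it would not add to the 17 higher genes.

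The change between the stages in DMSO embryos served as the background of normal development. Of 11650 genes 884 were called, 627 higher and 257 lower at 112 cells, and 564 of the higher and 79 of the lower changed at least 2-fold. KH.S164.28 rose from 5.33 ± 5.49 to 1561 ± 382 normalized counts on the joint scale (SD, n = 3 each; log2 fold change 8.33, SE 0.54, limma adjusted p = 2.66e-06). KH.C2.957 had 0 reads in all 3 DMSO libraries at 64 cells and 326 ± 91.3 normalized counts at 112 cells (limma adjusted p = 1.42e-06), which is at least 123-fold higher with a floor of 3 reads per library. KH.L20.26 fell from 1798 ± 138 to 317 ± 194 (log2 fold change -2.80, SE 0.48, limma adjusted p = 0.00338), or by a log2 value of -2.06 without DMSO replicate 3 at 112 cells. KH.C8.396 fell from 374 ± 49.3 to 55.1 ± 13.1 (log2 fold change -2.76, SE 0.22, limma adjusted p = 1.20e-05), or by a log2 value of -2.61, the larger fall of these 2, without that library. In U0126 embryos KH.S164.28 was at 4.67 ± 1.43 and 1606 ± 277, and KH.C2.957 at 1.33 ± 1.49 and 136 ± 36.8. In U0126 embryos 791 genes changed between the stages, 571 higher and 220 lower at 112 cells. Stage coincides with the deposited table, and the labels name no batch.

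Genes that rose during normal development held most of the U0126 calls at 112 cells. Of the 623 stage-risen genes tested there, 52 were lower and 17 higher with U0126, or 39 and 1 with the block. Of the 256 stage-fallen genes tested, limma called 0 with or without the block (9 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1. Of the 10436 genes not called between the stages, 8 were lower and 6 higher. With the replicate block 2035 genes differed between the stages, 1153 higher and 882 lower, among them all 884 of the unblocked calls. Without DMSO replicate 3 at 64 cells the unblocked count was 567, and it was 856 without DMSO replicate 3 at 112 cells. Without DMSO replicate 1, 2 or 3 at 64 cells, 108, 112 or 93 genes were called lower and 537, 484 or 474 higher. Without DMSO replicate 1, 2 or 3 at 112 cells, 279, 282 or 272 were called lower and 488, 494 or 584 higher.

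The difference of the U0126 effect between the stages was tested directly, since separate lists cannot show it. The effect differed in 18 genes of 11650, more negative at 112 cells in 17 and more positive in 1. KH.C12.115 had a log2 fold change of 0.34 (SE 0.62) at 64 cells and -5.73 (SE 0.58) at 112 cells, a difference of -6.08 (SE 0.88, limma adjusted p = 0.0286). KH.C2.629 was too low to be tested at 64 cells and had a log2 fold change of -5.56 (SE 0.65) at 112 cells, a difference of -5.52 (SE 0.80, limma adjusted p = 0.0286). On the joint scale KH.C12.115 was at 11.9 ± 7.16 in DMSO and 14.6 ± 7.72 in U0126 embryos at 64 cells. At 112 cells it was at 534 ± 193 and 10.2 ± 6.44. KH.C2.629 was at 6.56 ± 2.47 and 6.04 ± 1.05 at 64 cells, and at 167 ± 72.7 and 3.16 ± 3.59 at 112 cells. Neither gene had room at 64 cells for a fall of the size seen at 112 cells. KH.C2.995 had a log2 fold change of -0.01 (SE 0.23) at 64 cells and 2.10 (SE 0.24) at 112 cells, a difference of 2.11 (SE 0.34, limma adjusted p = 0.0417). The 17 more negative genes all had a positive stage change in DMSO embryos, but the DMSO libraries enter both estimates, and in the simulations without any effect 97.8% (88.2% to 100%) of the 17 most negative genes did too. With the block 31 genes were called, 30 more negative and 1 more positive, all 18 included. KH.C2.995 and KH.C12.115 lost their call whichever of the 12 libraries was left out (limma adjusted p 0.0511 to 0.160 and 0.0511 to 0.129), and KH.C2.629 in all but 1 of the 9 such fits that tested it (0.0212 to 0.100). The unblocked count was 0 to 9 when any of the 12 libraries was left out: 0 without DMSO replicate 3 at 64 cells or DMSO replicate 1 or 2 at 112 cells, and 9 without U0126 replicate 3 at 64 cells.

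Over the 10704 genes tested at both stages, both genes lower at 64 cells were among the 39 lower at 112 cells, where 0.0073 were expected (Fisher's exact test, two-sided, p = 1.29e-05, 2.59e-05 adjusted over both directions). With the block 16 genes were shared between 71 and 29 lower genes, where 0.19 were expected (Fisher's exact test, p = 1.45e-28, adjusted 2.91e-28), and 0 between 74 and 3 higher genes, where 0.02 were expected, so the higher lists were too short to test an overlap. No gene was called in opposite directions in either fit. The log2 fold changes of the stages correlated across genes with r = 0.47, a description only, since genes are not independent replicates. Fisher's exact test likewise counts genes as independent, so its p-values do not measure the variation between replicates. The overlap was 0 without DMSO replicate 2 or 3 or U0126 replicate 1 or 2 at 64 cells, and 1 without U0126 replicate 3 there. KH.L128.12 was not tested in the fits without a DMSO library at 64 cells, as the filter removed it.

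**Figure D4:**
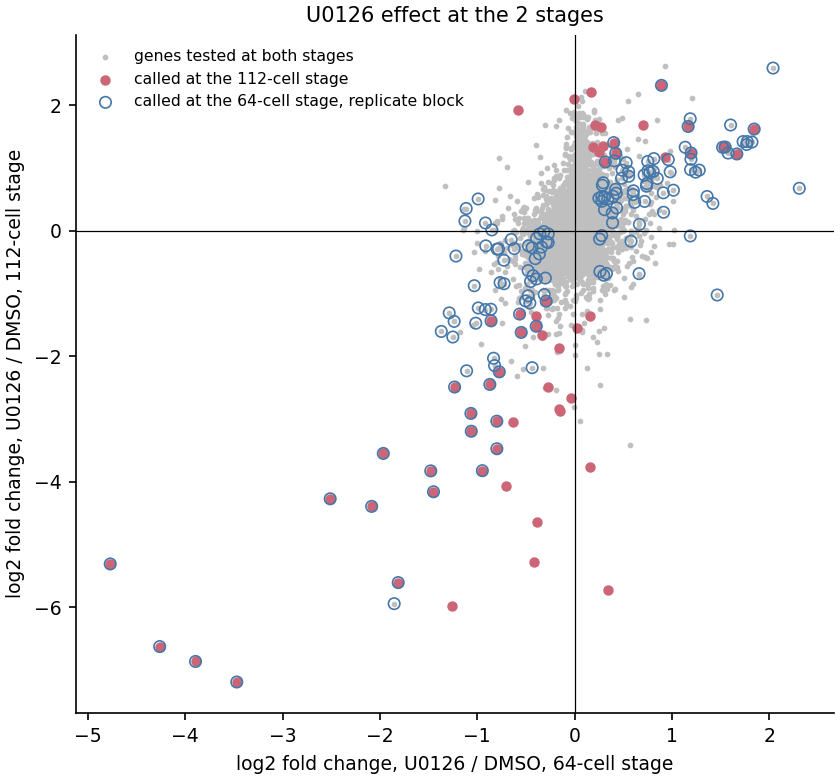
Log2 fold change of U0126 against DMSO at 64 cells (horizontal) and at 112 cells (vertical) for the 10704 genes tested at both stages, with red points called at 112 cells and blue circles called at 64 cells under the replicate block. 16 genes are lower under the block at both stages, and r across genes is 0.47.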

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

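Leaving out each library was decided before the data were examined, but using DMSO replicate 3 at 112 cells as a test of the 60 lower genes was chosen only after the result was seen. Testing the difference between the stages singled out 18 genes whose U0126 effect was not the same at 64 and 112 cells. Among them the difference in log2 fold change was 2.11 for KH.C2.995, -6.08 for KH.C12.115 and -5.52 for KH.C2.629. KH.C12.115 and KH.C2.629 were low at 64 cells in both treatments, which left little room for a fall there. Of 100 splits drawn within the stages, 8 gave at least 18 genes, the real one included. The highest of the others gave 44, so chance is not excluded for this count. These splits were drawn without regard to the replicate numbers and fitted without the block. All 8 kept the real grouping at 112 cells, as 10 of the drawn splits did, and the 90 without it gave at most 10. The count thus went with the 112-cell groups under most divisions of the 64-cell libraries.

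For the other counts the 10 splits of 6 libraries are too few for a share under 0.05. The real split was in each case the 1 split of 10 with as many genes: 2 called for U0126 at 64 cells, 83 at 112 cells and 884 between the stages in DMSO embryos, with 0 as the highest of the others each time. Of the 4 splits that part every same-number pair, the real one gave 146, 49 and 2035 genes under the replicate block, and the highest other gave 25, 0 and 0. The split with 25 exchanged DMSO and U0126 replicate 1 at 64 cells.

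Of the 60 genes lower with U0126 at 112 cells, 52 rose between the stages in DMSO embryos, while 6 rose and 4 fell in treated ones. A general delay of treated embryos would shrink the stage change of other genes as well. In genes not called for U0126, the change in the other arm was 0.950 (risers chosen in DMSO embryos) and 0.884 (chosen in U0126 embryos) of that in the choosing arm. For fallers it was 0.816 and 0.857, the lowest being 0.816 (bootstrap interval over genes, not libraries, 0.779 to 0.858). The 60 genes had 0.063, but they were chosen as low in U0126 embryos, and the others as not called, so this gap cannot decide. Over all 627 risers in DMSO embryos, called or not, the median log2 change was 2.23 in DMSO and 1.81 in U0126 embryos. Over all 257 fallers it was -0.80 and -0.70. These values argue against a delay that holds back most stage changes, while a smaller delay stays open. The DMSO library that stands apart does not by itself account for the pattern, as 38 of the 60 were called without it. That these genes may need MEK activity for their rise is a hypothesis, which these data cannot decide: they hold 1 inhibitor, no measure of ERK activity and no test of effects on other targets.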

How the results depend on the processing

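Tests chosen after seeing the data were the block in edgeR, other pseudocounts and the regularized log2 values. So were the blocked fits with libraries left out or all 12 fitted jointly. Unblocked edgeR with TMM was the test fixed beforehand and is counted here among the alternatives. It called 1 gene for U0126 at 64 cells, 83 at 112 cells, 879 between the stages and 14 for the difference of effects. KH.L128.12 missed the threshold under it (edgeR adjusted p = 0.0513). None of the 13 genes named from unblocked calls reversed under an alternative that tested it, and 63 of 291 of their values missed the threshold. These misses were uneven: 15 of 25 for KH.C2.995, 14 of 25 for KH.C12.115 and 9 of 18 for KH.C2.629, and 0 of 25 for each of the 4 stage genes. KH.L50.6 and KH.C9.872, named from the block, missed it under 14 and 17 of 22 alternatives. Except where a cause is given, it was not tested. The limma replicate block ended the calls of KH.C7.193 and KH.C9.131 and no other unblocked call of a named gene; the block in edgeR also ended that of KH.C2.629 (adjusted p = 0.0517; 2.88e-06 to 0.100 over its alternatives). Fits without a library have fewer samples, which lowers most counts.

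U0126 at 64 cells (2 genes) gave 146 with the replicate block, 132 with the block in edgeR, 18 with DESeq2, 5 in the joint fit with or without the block, and 1 with edgeR under either normalization (RLE or TMM), no filter, a pseudocount of 8, limma-voom or the regularized values. The blocked count was 112, 159 and 72 without replicate 1, 2 and 3 of every group. Leaving out a library gave 0 to 2.

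U0126 at 112 cells (83 genes) gave 49 with the replicate block, 54 with the block in edgeR, 230 with DESeq2, and 253 with the block in the joint fit, or 390 there without DMSO replicate 3. The blocked count was 83 (27 higher, 56 lower), 194 (120 higher, 74 lower) and 1201 (795 higher, 406 lower) without replicate 1, 2 and 3 of every group, against 4 higher and 45 lower with all. Leaving out a library gave 16 to 119. Of 23 alternatives 11 stayed within 1.5 times the count, among them edgeR, limma-voom, both pseudocounts, both filters and the regularized values.

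The stage difference in DMSO embryos (884 genes) gave 2035 with the replicate block, 2037 with the block in edgeR, 3079 with the block without DMSO replicate 3 at 112 cells, and 516 and 2400 with the block without replicate 2 and 3 of every group. Leaving out a library gave 567 to 856, and 19 of 25 alternatives stayed within 1.5 times.

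The difference of the U0126 effect between stages (18 genes) gave 31 with the replicate block, 49 with DESeq2, 10 without a filter, 31 with a pseudocount of 8, 135 with the block without DMSO replicate 3 at 112 cells, and 0, 0 and 103 with the block without replicate 1, 2 and 3 of every group. Leaving out a library gave 0 to 9.

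The overlap of the stages (2 genes) was 16 with the replicate block, 17 with the block in edgeR, 15 with DESeq2, and 1 with edgeR (RLE or TMM) or no filter. Leaving out a library gave 0 to 2. Gene list tests and their alternatives were not run, as no identifier could be matched to a name. At these depths a gene with 3 reads or fewer in a library cannot be told from 0.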

Other observations

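In this part the tests of depth, stage and preparation for DMSO replicate 3 at 112 cells, and all tests of the replicate numbers, were chosen only after the result was seen. Embryos of different replicate numbers differed in a set of genes in every group. By limma, 3970 of 11650 genes (34.1%) varied with the replicate number across the 12 libraries. In 23 genes the 4 libraries of a number lay at least 16-fold above or below all 8 others: 3 above and 5 below for number 1, 6 and 2 for number 2, and 5 and 2 for number 3, with median levels on the high side of 103, 111 and 122 normalized counts. When numbers were shuffled within groups, 100 shuffles gave at most 8 such genes against the real 23, which argues against chance among many genes. The largest ratio of read depth between libraries was 1.5, far from 16-fold. Different parents for each number may account for the pattern, but it cannot be told apart from a preparation or sequencing batch shared by a number, as the labels name 0 batches.

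DMSO replicate 3 at 112 cells lacked transcripts that all other libraries held. In it 210 genes lay at least 4-fold under each of the 11 others, against 0 to 4 genes in any other library, and 10 lay as far over. These genes had a median of 405 normalized counts in the other libraries and 32.7 in this one. Of the 209 tested for U0126 at 112 cells, 0 were called by limma, edgeR or DESeq2. None had an unadjusted limma p under 0.05, and their median log2 fold change was 1.24. Their choice by a low value in a DMSO library widens the DMSO spread and lowers the DMSO mean. Neither the 0 calls nor the 1.24 can therefore be read as a result about U0126. Lower read depth is argued against by the 358 reads expected in this library per gene (median). So is an outside library, as 7 of 7 markers of the other number 3 libraries took the number 3 level in it. Embryos further along the 64-to-112-cell change may account for the loss and stay open. The library lay at 69.7 on the first component, beyond the other 112-cell libraries at 23.0 to 45.1. That component was computed without leaving out the lacking genes, so this position may only restate their loss. For these genes the median log2 change between the stages in U0126 embryos was 0.022. It cannot decide either, as they were chosen as held in those libraries. RNA quality or library preparation stays open too, since 0 of these genes had a length or other transcript property at hand.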
